A study of Mus musculus with 16 samples.

How the data were processed

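Mouse bone-marrow-derived macrophages from frozen stocks of WT and Grn knockout mice were edited with Cas9 ribonucleoproteins against Mitf, Tfe3 and Tfeb or against Rosa26, and RNA was taken 10 days after transfection, per the labels' protocols. Libraries were made with a 3′ tag kit that adds unique molecular identifiers (UMIs) and were sequenced on a NovaSeq X, per the labels' protocols. The series design gives 16 animals in 4 groups of 4 and 4 batches with 1 animal of each group in each. The labels give 12-week-old male mice of the C57Bl/6J background with a human transferrin receptor knock-in.

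The submitters' processing notes name the genome build GRCm39, STAR 2.7.9a, Salmon 1.10.1, edgeR 4.6.2 and R 4.5.1, without saying which step each did. The handling of UMIs, the annotation release and filters were not given in the sources used here. The deposited count table held estimated counts per gene, per the values: 11.0% of the non-zero counts were not whole numbers. Both deposited tables, the counts and the normalised signal, were rounded to 2 significant digits, as tested on all values. The normalised signal deposited by the authors was CPM of the effective library size, that is, of the deposited library size times the deposited scaling factor, as tested on the values. The sample table gave the library size and the scaling factor per sample, per the file headers. The count table had 56980 rows, and 148 gene symbols were repeated, so genes were joined by Ensembl identifier.

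The estimated counts were rounded to whole numbers here and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on group, which left 15385, and libraries were scaled by TMM. CPM values in the text were computed here from these counts and factors, not taken from the authors' table. A quasi-likelihood model with a term per group and per batch was fitted over all 16 samples (glmQLFit with the robust option, then glmQLFTest). The tests gave the edit in WT, the edit in GrnKO, the loss of Grn in Rosa26 cells, the loss of Grn in TKO cells and the interaction. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. These p-values measure the spread between samples, and the biological coefficient of variation was 12.0%. Changes are log2 fold changes ± SE, and group levels are means ± SD.

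Gene lists were written from textbook knowledge. There were 33: lysosomal hydrolases, lysosomal membrane proteins, V-ATPase subunits, Rag GTPase and folliculin signalling, autophagy machinery, textbook MiT/TFE targets, disease-associated microglia and lipid-associated macrophage genes, LXR targets, cholesterol synthesis, lipid uptake and droplets, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, alternative activation, complement, MHC class II presentation, p53 targets, cell cycle, integrated stress response, unfolded protein response, glycolysis and hypoxia response, nuclear oxidative phosphorylation, antioxidant and iron handling, osteoclast genes, macrophage identity, stromal cell markers, neutrophil markers, lymphocyte markers, mast cell and basophil markers, dendritic cell markers, erythroid and megakaryocyte markers, immediate early and heat shock genes, mitochondrially encoded genes, cytosolic ribosomal proteins. The 27 lists with 5 or more tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry, both also chosen in advance. The first compares a list with the other genes, while fry asks whether a list's genes move one way. Lists share genes, such as the MiT/TFE targets and the lysosomal lists. The genes named in the text were the targeted genes and Tfec, and, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean of 5 CPM or more in a group compared and 1 direction in all 4 batches (5 and 5 for the interaction). Up to 4 genes of smallest p per list and comparison were added. Other genes are named as chosen after their values were seen. Some single genes of the lists are not reported by name here. The design, lists, rule and the first group of alternative settings below were fixed before the data were examined.

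Batch was a term of the model because the series design and the labels give it. As a check, deviations from the group means were correlated between libraries of the same batch. Rosa26 and TKO libraries of the same genotype and batch had mean correlations of 0.275 in WT and 0.276 in GrnKO, with each pair over 0.1. Across genotypes the mean was 0.0802 on autosomal genes, with a highest other pairing of 0.112 (exact permutation p = 0.0191, 576 pairings). The correlation of log2 CPM between any 2 libraries lay between 0.938 and 0.993.

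The alternative settings chosen in advance were RLE scaling, no filter on low counts, a mean of 5 CPM or more, DESeq2 1.42.0, limma-trend on the log2 of the authors' CPM, a model with no replicate block (without batch), only the 8 samples compared, and leaving out each library in turn. Alternatives added after seeing the data were counts refined from both rounded tables, libraries thinned to equal depth, the 10 libraries with little Y-linked signal, no robust option, and a block for each of the 8 combinations of genotype and batch. For contrasts with shared libraries, unchanged groups were simulated. Other splits of the samples were drawn: all 35 for groups of 4 against 4, and 100 for the interaction and the correlations.

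Each test was checked on simulated counts with known changes, drawn from the real means and library sizes. Of 100 genes changed 1.5-fold and 100 changed 2-fold, the test recovered 55 and 75 for the edit in WT, 54 and 81 for the edit in GrnKO, 50 and 74 for the loss of Grn in Rosa26 cells, 56 and 64 for it in TKO cells, and 20 and 49 for the interaction. Calls among unchanged genes numbered 11, 11, 8, 6 and 4 in that order. With a true remaining effect of 25% simulated in TKO cells, the median over called genes was 23.4%.

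Rounding of the deposited counts left a median half-width of 1.85% for counts of 100 or more. The handling of PCR copies is unknown, so counts are not taken as independent molecules and no counting intervals are given. Genes with near-identical copies or overlapping identifiers are uncertain, among them ribosomal protein genes with pseudogenes, Ly6a, Saa3, the Ifit genes, H2 genes and Pakap. The reference table at hand was of GRCm38.p6 and the deposited values of GRCm39, so it served only for chromosome membership and gene order, and no coordinates are given. It matched 13490 of the tested identifiers (87.7%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.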

Results

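Gene expression was measured by 3′ tag sequencing of polyadenylated RNA in mouse bone-marrow-derived macrophages grown in M-CSF. The cells came from WT mice or from mice without Grn (GrnKO), the gene of the secreted and lysosomal protein progranulin. Each was transfected with Cas9 and guides against Mitf, Tfe3 and Tfeb, which encode the MiT/TFE transcription factors of lysosomal and autophagy genes (the cells called TKO here), or against the Rosa26 locus as the control edit. RNA was taken 10 days later. There were 4 groups of 4 samples in 4 batches, and each batch held 1 sample of each group. The total of the counts per library lay between 7069445 and 22469333 in WT Rosa26, with the lowest in replicate 1, 16246549 and 21463565 in WT TKO, 28431505 and 32969401 in GrnKO Rosa26 and 18387499 and 28511718 in GrnKO TKO, so depth differed with genotype in the Rosa26 cells.

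The GrnKO Rosa26 macrophages stood apart from the other 3 groups on the first principal component, which held 37.4% of the variance. Their scores were 45.7 to 55.7, against -56.1 to 10.6 in all other libraries. GrnKO TKO replicate 2 was the nearest of these, at 10.6. The second component (14.9%) held WT Rosa26 replicate 1, the shallowest library, at 63.4. The third (9.71%) held the WT libraries of batch 3, at -38.8 and -42.0. Cytosolic ribosomal protein genes took 7.54 ± 0.511% (SD, n = 4) of the counts in WT Rosa26, 7.71 ± 0.328% in WT TKO, 5.70 ± 0.255% in GrnKO Rosa26 and 6.74 ± 0.389% in GrnKO TKO.

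**Figure D1:**
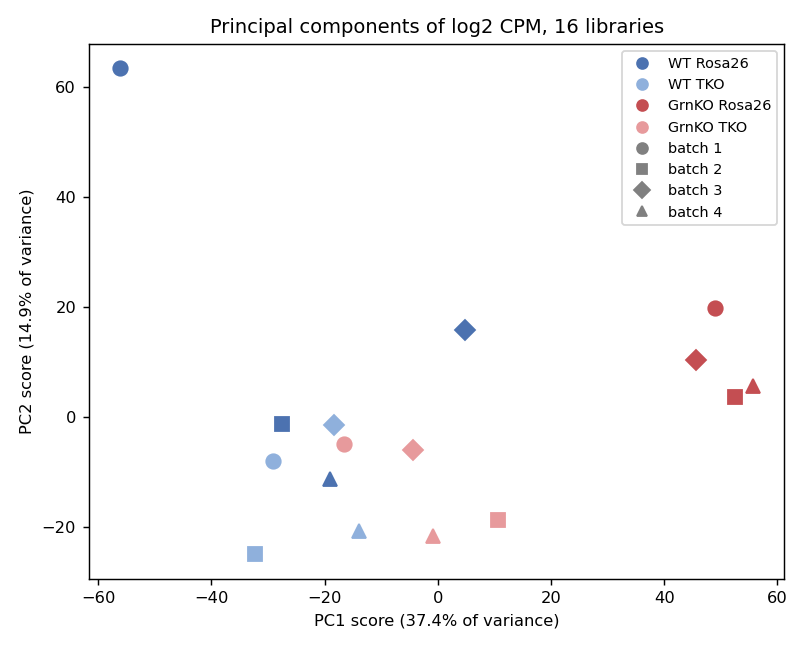
Scores of the 16 libraries on the first and second principal components of log2 CPM. Axis titles give the share of variance of each, and marker shape gives the batch. The 4 GrnKO Rosa26 libraries lie at 45.7 to 55.7 on the first component, above all others.

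Transcripts of the sex chromosomes differed between libraries of the same group, although the labels give male mice for all of them. Xist, the RNA of the inactive X chromosome, and the Y-linked Ddx3y were chosen after their values were seen. In 10 libraries Xist lay at 169 to 268 CPM and Ddx3y at 0.0551 to 1.22 CPM. The 2 WT libraries of batch 3 had Ddx3y at 108 to 112 CPM and Xist at 2.92 to 3.94 CPM. The 2 GrnKO libraries of batch 4 had Ddx3y at 97.2 to 122 CPM and Xist at 15.6 to 25.2 CPM. The 2 WT libraries of batch 2 had both, with Ddx3y at 31.6 to 34.2 CPM and Xist at 212 to 217 CPM. The Rosa26 and TKO libraries of a genotype and batch had like values, so the comparisons of editing were balanced for this difference and those of genotype were not.

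**Figure D2:**
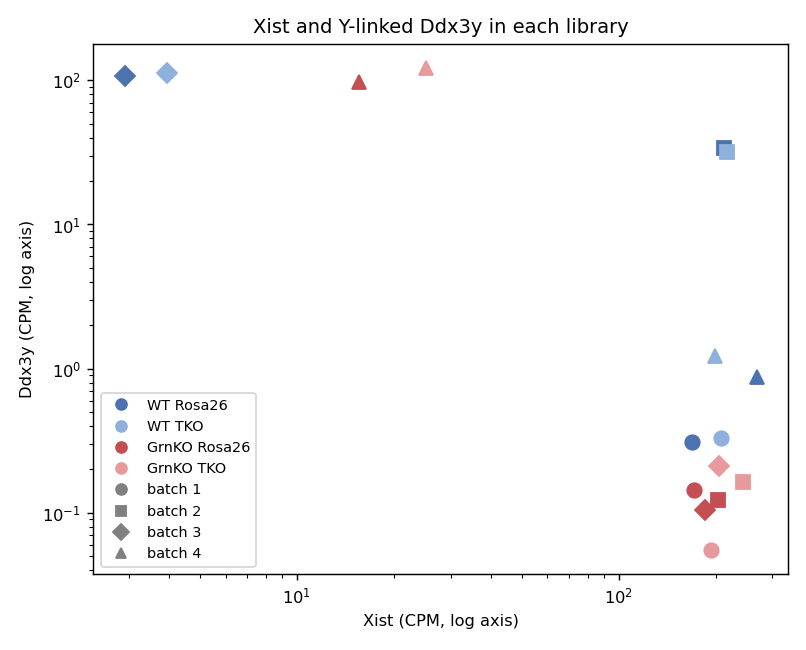
Xist against Ddx3y in CPM per library, on log axes. The 10 libraries with little Y-linked signal lie at low Ddx3y and high Xist, and the WT pairs of batches 2 and 3 and the GrnKO pair of batch 4 lie apart from them.

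Grn (ENSMUSG00000034708) was at 3244 ± 354 CPM (SD, n = 4) in WT Rosa26 and 3009.9 ± 328 in WT TKO, against 48.6 ± 4.80 in GrnKO Rosa26 and 48.4 ± 6.79 in GrnKO TKO. No library crossed between genotypes: Grn spanned 2875 to 3693 and 2522 to 3224 CPM in the WT groups and 44.2 to 54.8 and 40.7 to 56.1 CPM in the GrnKO groups. The Grn fold change was -6.06 ± 0.13, adjusted p = 3.2e-16 in Rosa26 cells (log2 ± SE of edgeR, the form of all fold changes here) and -5.96 ± 0.13, adjusted p = 4.2e-16 in TKO cells. Tfe3 (ENSMUSG00000000134) was at 319 ± 69.8 CPM in WT Rosa26 and 170.1 ± 27.0 in WT TKO, and at 236 ± 18.6 in GrnKO Rosa26 and 166 ± 29.0 in GrnKO TKO. It fell with editing in WT (-0.90 ± 0.17, adjusted p = 0.0108, per batch -1.28 to -0.72) and in GrnKO (-0.51 ± 0.17, adjusted p = 0.0351, per batch -0.79 to -0.35). These falls were not shown to differ (interaction 0.39 ± 0.24, adjusted p = 0.299). By library Tfe3 spanned 229.8 to 400.1 CPM in WT Rosa26, 136 to 199 in WT TKO, 218 to 262 in GrnKO Rosa26 and 135 to 205 in GrnKO TKO.

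Mitf (ENSMUSG00000035158) was at 189.7 ± 23.0, 159.9 ± 19.7, 144 ± 10.2 and 171 ± 13.6 CPM in WT Rosa26, WT TKO, GrnKO Rosa26 and GrnKO TKO. Editing gave -0.25 ± 0.09, adjusted p = 0.172 in WT and 0.25 ± 0.09, adjusted p = 0.0490 in GrnKO, with an interaction of 0.49 ± 0.13, adjusted p = 0.0187. Mitf was lower in GrnKO than in WT Rosa26 cells (-0.39 ± 0.09, adjusted p = 0.00219). By library it spanned 165 to 216, 132 to 175, 133 to 154 and 158 to 187 CPM in the same order. Tfeb (ENSMUSG00000023990) was at 80.7 ± 9.92, 70.7 ± 7.41, 69.8 ± 2.60 and 59.1 ± 13.4 CPM and passed no test, with -0.19 ± 0.12, adjusted p = 0.474 for editing in WT and -0.25 ± 0.12, adjusted p = 0.133 in GrnKO. By library Tfeb spanned 67.6 to 89.0, 60.3 to 77.2, 67.8 to 73.4 and 49.5 to 78.9 CPM. Tfec (ENSMUSG00000029553), the paralogue that was not targeted, was at 6.08 ± 1.14, 5.04 ± 0.729, 11.5 ± 0.593 and 7.65 ± 1.37 CPM. It was higher in GrnKO than in WT cells of either edit (0.92 ± 0.16, adjusted p = 1.4e-04 in Rosa26, 0.60 ± 0.16, adjusted p = 0.0388 in TKO) and fell with editing in GrnKO (-0.59 ± 0.15, adjusted p = 0.00643). Tags at the 3′ end count the mRNA whether or not it carries an edit, so the levels of Mitf, Tfe3 and Tfeb do not check the editing. The Grn level does check the genotype labels in every library.

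**Figure D3:**
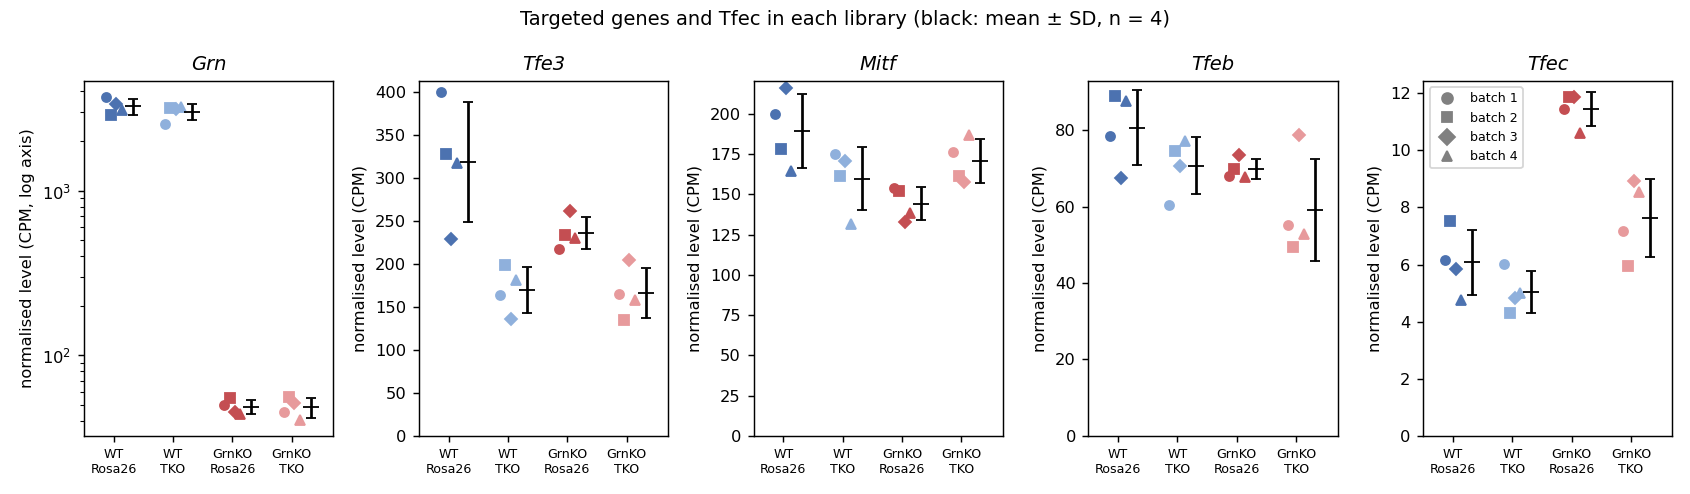
CPM per library of Grn, Mitf, Tfe3, Tfeb and Tfec in the 4 groups, with group means and SD (n = 4). Grn separates the genotypes in all 16 libraries, and Tfe3 is lower in TKO than in Rosa26 means of both genotypes.

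The first comparison asked what the loss of progranulin changed in macrophages with the control edit (GrnKO against WT, Rosa26, n = 4 per group). Genes of the lysosome, the proton pump that acidifies it, autophagy and cholesterol synthesis rose together, and genes of complement and of ribosomal proteins fell. With an estimated correlation between genes the list call was lost for lysosomal hydrolases (adjusted p = 0.0702) and ribosomal proteins (adjusted p = 0.0855). Among genes with a mean of 5 CPM or more in a group and 1 direction in all batches, to which statements on the largest changes refer throughout, the largest rise was in Dio2, a thyroid hormone deiodinase, from 1.40 ± 0.370 to 65.6 ± 7.39 CPM (SD). Mgll, the monoacylglycerol lipase, rose from 0.837 ± 0.383 to 20.7 ± 2.81 CPM. After Grn itself the largest fall was in Cx3cr1, the fractalkine receptor, from 34.0 ± 13.0 to 3.78 ± 1.00 CPM. Of 15385 genes tested, 3548 rose and 3310 fell, 6858 in all, and 1573 changed more than 2-fold (426 rose and 1147 fell). With limma-trend on the authors' CPM the split was 4793 rises and 2509 falls (65.6% rises against 51.7%).

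Among single genes, Dio2 (5.55 ± 0.17), Mgll (4.77 ± 0.25), Adamts1 (3.74 ± 0.19), Cd28 (2.98 ± 0.14) and Fabp4 (2.34 ± 0.14) rose, all with an adjusted p of 7.2e-10 or less. Cd28 is a costimulatory receptor best known from T cells, and Fabp4 is a fatty acid carrier. Cx3cr1 (-3.15 ± 0.36), Ly6a (-2.86 ± 0.44), Pamr1 (-2.73 ± 0.19), Arg1 (-2.43 ± 0.14) and Saa3 (-2.38 ± 0.29) fell, with an adjusted p of 3.0e-04 or less. Arg1 encodes arginase and stood at 13.1 ± 1.62 CPM in WT and 2.42 ± 0.265 in GrnKO. Fam171a2, which lies next to Grn in the gene order, rose by 2.67 ± 0.25 from 0.925 ± 0.155 to 5.86 ± 1.01 CPM. The neighbour on the other side, Slc25a39, which was chosen after its values were seen, had 0.30 ± 0.07 (adjusted p = 0.00326).

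Of the lysosomal hydrolases, 33 of 49 rose and 7 fell (34 and 7 adjusted over the list alone), camera adjusted p = 6.3e-07 but adjusted p = 0.0702 with an estimated correlation. They included Naglu, an enzyme of heparan sulfate breakdown, from 54.0 ± 6.52 to 127 ± 4.21 CPM (1.24 ± 0.09), and Gla (0.88 ± 0.07) and Galns (1.25 ± 0.11). Of the lysosomal membrane proteins, 24 of 32 rose and 1 fell (24 and 1 adjusted over the list alone), camera adjusted p = 1.2e-09, led by Slc29a3 (1.05 ± 0.08), Slc36a1 (1.18 ± 0.09) and Mfsd12 (1.03 ± 0.09). Of the V-ATPase subunits, 16 of 18 rose and 0 fell (16 and 0 adjusted over the list alone), camera adjusted p = 1.2e-09, with Atp6v1b2 (0.69 ± 0.06), Atp6v1g1 (0.96 ± 0.09) and Atp6v0d1 (0.73 ± 0.07) among them. Of the genes of Rag GTPase and folliculin signalling, which control the nuclear entry of MiT/TFE factors, 10 of 15 rose and 1 fell (10 and 1 adjusted over the list alone), camera adjusted p = 7.5e-04. Rragd (1.1 ± 0.09) and Fnip2 (0.98 ± 0.10) were examples. Of the autophagy machinery, 17 of 34 rose and 5 fell (17 and 5 adjusted over the list alone), camera adjusted p = 4.9e-04, with Gabarapl1 (1.16 ± 0.08), Tecpr1 (1.26 ± 0.09) and Ulk1 (1.00 ± 0.12). Of the textbook MiT/TFE targets, many of which are also in the lists above, 18 of 23 rose and 2 fell (19 and 2 adjusted over the list alone), camera adjusted p = 6.8e-09. Gpnmb, a target of MITF and a glycoprotein of lysosomes and the cell surface, rose by 0.78 ± 0.09 from 2708 ± 406 to 4618 ± 80.7 CPM.

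Of the genes of cholesterol synthesis, 21 of 23 rose and 0 fell (21 and 0 adjusted over the list alone), camera adjusted p = 7.2e-11, among them Insig1 (1.08 ± 0.09) and Hmgcs1 (1.01 ± 0.09). Of the LXR targets, which export cholesterol and make fatty acids, 7 of 11 rose and 0 fell (8 and 0 adjusted over the list alone), camera adjusted p = 0.00316 but adjusted p = 0.173 with an estimated correlation, with Abcg1 (1.40 ± 0.13) the example of smallest p. Of the genes of lipid uptake and droplets, 8 of 15 rose and 2 fell (8 and 3 adjusted over the list alone), camera adjusted p = 4.0e-04 but adjusted p = 0.0519 with an estimated correlation, with Hilpda (1.36 ± 0.09) and Plin3 (1.19 ± 0.10) beside Fabp4. In the list of the unfolded protein response, 7 of 19 rose and 0 fell (7 and 0 adjusted over the list alone), camera adjusted p = 0.0491 but adjusted p = 0.432 with an estimated correlation, with Sdf2l1 (1.20 ± 0.13) and Dnajb11 (0.48 ± 0.07). The iron exporter Slc40a1 (1.73 ± 0.11) and the integrin Itgb3 (2.01 ± 0.14) rose too, while their lists did not pass the test. For antioxidant and iron handling 5 of 17 rose and 7 fell (6 and 8 adjusted over the list alone), camera adjusted p = 0.745, with a median of -0.18, a mean of 0.09 and an upward test. For osteoclast genes 4 of 10 rose and 3 fell (4 and 3 adjusted over the list alone), camera adjusted p = 0.192.

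Of the complement genes, 2 of 10 rose and 6 fell (2 and 6 adjusted over the list alone), camera adjusted p = 7.4e-05. C1qa, of the initiating complement complex, fell by 0.94 ± 0.07 from 647 ± 42.4 to 339 ± 38.2 CPM, and C3 (-1.74 ± 0.20) and Itgam (-1.46 ± 0.12) fell too. Of the inflammatory cytokines and NF-kB targets, 3 of 21 rose and 9 fell (3 and 10 adjusted over the list alone), camera adjusted p = 0.0398 but adjusted p = 0.173 with an estimated correlation. Nlrp3 (-1.02 ± 0.12) and Nfkbiz (-1.55 ± 0.18) fell, while the chemokines Ccl4 (1.17 ± 0.09) and Ccl3 (1.08 ± 0.14) rose. Of the alternative activation genes, 1 of 9 rose and 4 fell (1 and 4 adjusted over the list alone), camera adjusted p = 0.00316, with Arg1, Folr2 (-1.01 ± 0.07) and Il10 (-1.25 ± 0.22) lower and Clec10a (0.40 ± 0.12) higher. Of the macrophage identity genes, 4 of 17 rose and 6 fell (4 and 7 adjusted over the list alone), camera adjusted p = 0.0205 but adjusted p = 0.0985 with an estimated correlation. Adgre1 (-1.01 ± 0.10), the gene of F4/80, fell and Mertk (0.95 ± 0.10) rose. Of the immediate early and heat shock genes, 3 of 19 rose and 7 fell (3 and 7 adjusted over the list alone), camera adjusted p = 0.00959 but adjusted p = 0.173 with an estimated correlation, with Fos (-1.17 ± 0.08) and Nr4a1 (-1.34 ± 0.09). Of the cytosolic ribosomal protein genes, which have many near-identical pseudogenes, 1 of 67 rose and 57 fell (1 and 57 adjusted over the list alone), camera adjusted p = 9.0e-21 but adjusted p = 0.0855 with an estimated correlation, with Rps27 (-0.86 ± 0.07) and Rpl10 (-1.18 ± 0.10). Interferon-stimulated genes went both ways (7 of 35 rose and 8 fell, 7 and 8 adjusted over the list alone, camera adjusted p = 0.60), with a median of 0.01 and a downward test.

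Of 27 lists with 5 or more tested genes, 16 passed (10 up and 6 down), and 8 of these also passed with an estimated correlation: lysosomal membrane proteins, V-ATPase subunits, Rag GTPase and folliculin signalling, autophagy machinery, textbook MiT/TFE targets, cholesterol synthesis, complement, alternative activation. Of the 6858 genes called, 6074 had 1 direction in all 4 batches. The 2 groups differed in depth and in Xist and Y-linked transcripts, as given above. The 10 libraries of little Y-linked signal cannot test the latter, as only batch 1 holds both genotypes there.

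**Figure D4:**
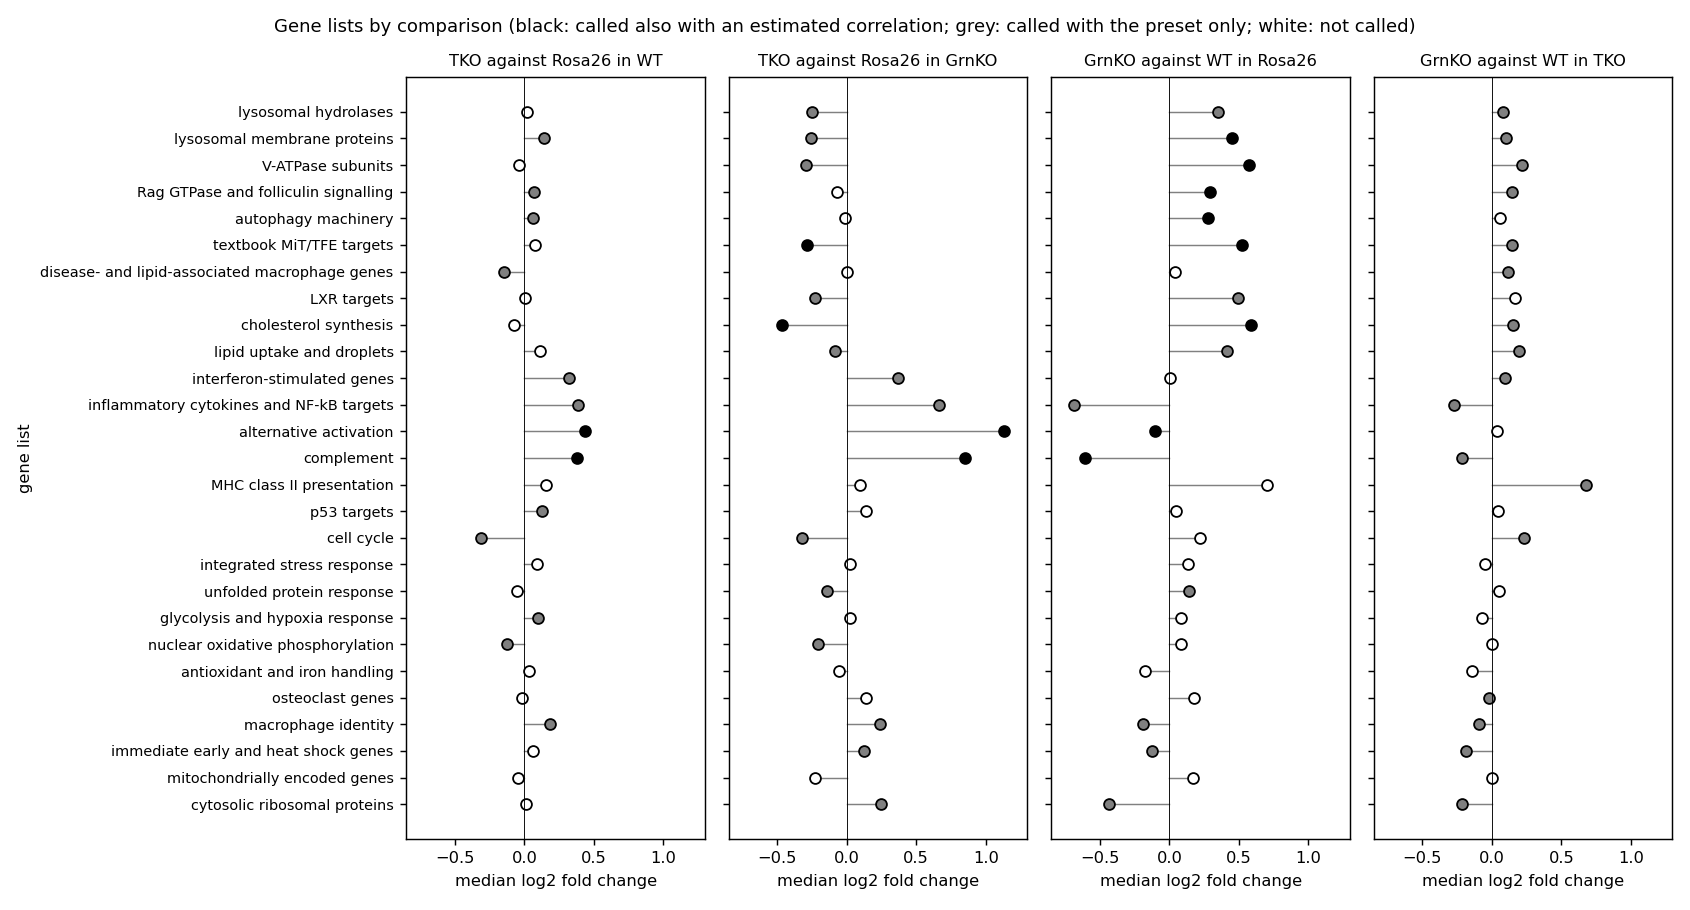
Median log2 fold change of each gene list with 5 or more tested genes, in the 4 comparisons, with lists past the camera test in black where they also passed with an estimated correlation, in grey where they did not, and the other lists in white. The lysosomal, V-ATPase and cholesterol lists are above 0 for the loss of Grn in Rosa26 cells and below 0 for the triple edit in GrnKO cells.

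The second comparison asked what editing of Mitf, Tfe3 and Tfeb changed in macrophages without progranulin (TKO against Rosa26, GrnKO, n = 4 per group). Genes of lysosomes, the V-ATPase, cholesterol synthesis and oxidative phosphorylation fell, and genes of complement, alternative activation, interferon response and ribosomal proteins rose. With an estimated correlation the call was lost for lysosomal hydrolases (adjusted p = 0.105), lysosomal membrane proteins (adjusted p = 0.101), the V-ATPase (adjusted p = 0.0867), oxidative phosphorylation (adjusted p = 0.383), interferon-stimulated genes (adjusted p = 0.214) and ribosomal proteins (adjusted p = 0.256). Dio2 fell from 65.6 ± 7.39 to 2.32 ± 0.756 CPM (SD) and Mgll from 20.7 ± 2.81 to 1.27 ± 0.426 CPM. F13a1, the A chain of coagulation factor XIII, rose from 0.373 ± 0.168 to 19.8 ± 4.81 CPM, and the surface antigen gene Ly6a from 0.767 ± 0.284 to 11.6 ± 3.43 CPM. Of 15385 genes, 2271 rose and 2740 fell, 5011 in all. More than 2-fold changes were found for 924 genes, of which 759 rose and 165 fell. With limma-trend on the authors' CPM 1661 rose and 3223 fell (34.0% rises against 45.3%).

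The largest rises included F13a1 (5.69 ± 0.29), Ly6a (3.96 ± 0.41), Ccl8 (2.96 ± 0.24), Pamr1 (2.7 ± 0.19), Saa3 (2.65 ± 0.29), Cp (2.45 ± 0.17) and Lifr (2.34 ± 0.10), with an adjusted p of 1.0e-04 or less. Ccl8 is a monocyte chemokine and Cp the ferroxidase ceruloplasmin. The largest falls included Dio2 (-4.82 ± 0.15), Mgll (-3.99 ± 0.22), Cdkn1c (-3.36 ± 0.22), Adamts1 (-2.43 ± 0.16), Fabp4 (-2.32 ± 0.13) and Mfge8 (-2.10 ± 0.12), with an adjusted p of 9.5e-08 or less. Cdkn1c is an inhibitor of cyclin-dependent kinases and Mfge8 a bridge for the uptake of dying cells.

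Of the lysosomal hydrolases, 6 of 49 rose and 31 fell (6 and 32 adjusted over the list alone), camera adjusted p = 6.6e-06 but adjusted p = 0.105 with an estimated correlation, with Galns (-1.02 ± 0.11), Naglu (-0.76 ± 0.09), Hexa (-0.64 ± 0.07) and Psap (-0.79 ± 0.09). Naglu stood at 127 ± 4.21 CPM in Rosa26 and 74.9 ± 6.83 in TKO. Of the lysosomal membrane proteins, 1 of 32 rose and 17 fell (1 and 20 adjusted over the list alone), camera adjusted p = 1.5e-05 but adjusted p = 0.101 with an estimated correlation, with Slc29a3 (-0.59 ± 0.08) and Lamp1 (-0.40 ± 0.06). Of the V-ATPase subunits, 0 of 18 rose and 15 fell (0 and 16 adjusted over the list alone), camera adjusted p = 1.3e-06 but adjusted p = 0.0867 with an estimated correlation, with Atp6v1b2 (-0.58 ± 0.06) and Atp6v0c (-0.54 ± 0.08). Among the textbook MiT/TFE targets, 0 of 23 rose and 12 fell (0 and 13 adjusted over the list alone), camera adjusted p = 4.2e-05. Gpnmb fell by 1.09 ± 0.09 from 4618 ± 80.7 to 2168 ± 203 CPM, and Ctsk (-1.50 ± 0.22), a collagen-degrading cathepsin, fell too. Autophagy genes and genes of Rag GTPase and folliculin signalling did not pass as lists (camera adjusted p = 0.117 and camera adjusted p = 0.158), although Gabarapl1 (-0.70 ± 0.08), Tecpr1 (-0.61 ± 0.09), Ulk1 (-0.63 ± 0.11) and Lamtor4 (-0.48 ± 0.08) fell.

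Of the genes of cholesterol synthesis, 0 of 23 rose and 19 fell (0 and 19 adjusted over the list alone), camera adjusted p = 4.2e-12, among them Cyp51 (-0.79 ± 0.08) and Mvk (-0.87 ± 0.11). Among LXR targets, 2 of 11 rose and 3 fell (2 and 6 adjusted over the list alone), camera adjusted p = 0.0288 but adjusted p = 0.338 with an estimated correlation, with Abcg1 (-0.88 ± 0.12). Among genes of lipid uptake and droplets, 2 of 15 rose and 6 fell (2 and 6 adjusted over the list alone), camera adjusted p = 0.00924 but adjusted p = 0.172 with an estimated correlation, with Fabp5 (-1.24 ± 0.16). Of the genes of nuclear oxidative phosphorylation, 0 of 56 rose and 28 fell (0 and 29 adjusted over the list alone), camera adjusted p = 1.8e-04 but adjusted p = 0.383 with an estimated correlation, with Ndufb3 (-0.73 ± 0.09) and Ndufa1 (-0.54 ± 0.07). The mitochondrially encoded genes did not pass (0 of 13 rose and 5 fell, 0 and 6 adjusted over the list alone, camera adjusted p = 0.0586). Of the cell cycle genes, 1 of 35 rose and 15 fell (1 and 15 adjusted over the list alone), camera adjusted p = 0.00103 but adjusted p = 0.383 with an estimated correlation, with the mitotic kinase gene Cdk1 (-0.80 ± 0.10). In the unfolded protein response, 0 of 19 rose and 7 fell (0 and 7 adjusted over the list alone), camera adjusted p = 0.0156 but adjusted p = 0.342 with an estimated correlation. The osteoclast genes did not pass as a list (camera adjusted p = 0.164, median 0.14, mean -0.26, downward test), nor did the genes of the integrated stress response (1 of 19 rose and 4 fell, 1 and 3 adjusted over the list alone, camera adjusted p = 0.705, median 0.02, mean -0.01, downward test).

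Of the complement genes, 7 of 10 rose and 0 fell (7 and 0 adjusted over the list alone), camera adjusted p = 1.5e-09. C1qa rose by 1.17 ± 0.07 from 339 ± 38.2 to 758 ± 28.8 CPM, and Itgam (1.27 ± 0.12) and C3 (1.43 ± 0.19) rose too. Of the alternative activation genes, 8 of 9 rose and 0 fell (8 and 0 adjusted over the list alone), camera adjusted p = 1.7e-13, with Folr2 (0.95 ± 0.07), Mgl2 (1.44 ± 0.17) and Arg1 (1.13 ± 0.14) beside F13a1. Among interferon-stimulated genes, 14 of 35 rose and 1 fell (15 and 2 adjusted over the list alone), camera adjusted p = 3.7e-06 but adjusted p = 0.214 with an estimated correlation, with Ifi27l2a (1.83 ± 0.08) and Irf7 (1.53 ± 0.24). Among inflammatory cytokines and NF-kB targets, 10 of 21 rose and 2 fell (10 and 2 adjusted over the list alone), camera adjusted p = 1.5e-04 but adjusted p = 0.0503 with an estimated correlation, with Ccl5 (1.94 ± 0.22) and Nfkbiz (1.35 ± 0.18) higher and Ccl4 (-0.99 ± 0.09) lower. Of the macrophage identity genes, 8 of 17 rose and 2 fell (9 and 2 adjusted over the list alone), camera adjusted p = 0.00119 but adjusted p = 0.0520 with an estimated correlation. Cx3cr1 rose by 2.28 ± 0.36 from 3.78 ± 1.00 to 18.2 ± 5.82 CPM. Among immediate early and heat shock genes, 7 of 19 rose and 2 fell (8 and 2 adjusted over the list alone), camera adjusted p = 0.0139 but adjusted p = 0.243 with an estimated correlation, with Fos (0.63 ± 0.08) and Klf4 (0.96 ± 0.13). Of the cytosolic ribosomal proteins, 43 of 67 rose and 1 fell (46 and 1 adjusted over the list alone), camera adjusted p = 3.9e-10 but adjusted p = 0.256 with an estimated correlation, with Rpl26 (0.65 ± 0.08) and Rps27 (0.46 ± 0.07). In all, 17 of 27 lists passed (7 up and 10 down), 4 of them (textbook MiT/TFE targets, cholesterol synthesis, complement, alternative activation) also with an estimated correlation. Of the genes called, 4920 had 1 direction in all 4 batches.

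The third comparison asked what the same edit changed in WT macrophages (TKO against Rosa26, WT, n = 4 per group). F13a1 again had the largest rise, from 0.923 ± 0.425 to 52.7 ± 10.8 CPM (SD), and Ccl8 rose from 12.4 ± 5.58 to 52.8 ± 11.5 CPM and Ly6a from 5.53 ± 1.68 to 23.5 ± 11.6 CPM. Gpnmb fell from 2708 ± 406 to 1543 ± 163 CPM. The lists of alternative activation, complement, interferon and inflammatory genes rose. With an estimated correlation the call was lost for interferon (adjusted p = 0.293) and inflammatory genes (adjusted p = 0.0673). The lysosomal hydrolases and the V-ATPase subunits did not pass the test. Of 15385 genes, 336 rose and 179 fell, 515 in all, and 66 rose and 16 fell more than 2-fold. With limma-trend on the authors' CPM 472 rose and 125 fell (79.1% rises against 65.2%).

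The largest rises were led by F13a1 (5.89 ± 0.29), Ccl8 (2.17 ± 0.24), Ly6a (2.03 ± 0.35), Clec4n (1.91 ± 0.27), Saa3 (1.81 ± 0.27), Slc13a3 (1.70 ± 0.23), Cp (1.57 ± 0.16), Mmp14 (1.48 ± 0.21) and Lifr (1.47 ± 0.10), with an adjusted p of 0.00830 or less. Clec4n is the fungal pattern receptor Dectin-2, Slc13a3 a carrier of dicarboxylates and Lifr the receptor of leukaemia inhibitory factor. The largest falls included Adra1a (-1.26 ± 0.16), Cpe (-1.15 ± 0.11), Cdkn1c (-1.14 ± 0.26), Fgf13 (-1.03 ± 0.23), Serpinb6b (-1.03 ± 0.10), Nes (-1.01 ± 0.16) and Fabp4 (-0.94 ± 0.15), with an adjusted p of 0.0244 or less.

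Of the alternative activation genes, 5 of 9 rose and 1 fell (5 and 1 adjusted over the list alone), camera adjusted p = 1.3e-12, with Mgl2 (1.32 ± 0.19) and Mrc1 (0.43 ± 0.09). Of the complement genes, 4 of 10 rose and 0 fell (8 and 1 adjusted over the list alone), camera adjusted p = 3.7e-06, and C1qa rose by 0.56 ± 0.07 from 647 ± 42.4 to 953 ± 56.7 CPM. Among interferon-stimulated genes, 5 of 35 rose and 0 fell (13 and 1 adjusted over the list alone), camera adjusted p = 1.7e-05 but adjusted p = 0.293 with an estimated correlation, with Ifit2 (1.22 ± 0.25) and Ifi27l2a (0.43 ± 0.08). Among inflammatory genes, 7 of 21 rose and 2 fell (9 and 2 adjusted over the list alone), camera adjusted p = 1.7e-04 but adjusted p = 0.0673 with an estimated correlation, with Cxcl1 (1.38 ± 0.28) and Ptgs2 (0.86 ± 0.15) higher and Ccl4 (-0.72 ± 0.09) lower. Of the macrophage identity genes, 2 of 17 rose and 0 fell (5 and 1 adjusted over the list alone), camera adjusted p = 0.00446 but adjusted p = 0.146 with an estimated correlation. Lists past the test with few called genes were p53 targets (2 of 23 rose and 0 fell, 4 and 0 adjusted over the list alone, camera adjusted p = 0.00446 but adjusted p = 0.293 with an estimated correlation) and glycolysis and hypoxia response (2 of 23 rose and 1 fell, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0431 but adjusted p = 0.405 with an estimated correlation). In these, Fas (0.75 ± 0.14) and Hk2 (0.67 ± 0.09) rose. Of the cell cycle genes, 0 of 35 rose and 4 fell (0 and 13 adjusted over the list alone), camera adjusted p = 1.7e-06 but adjusted p = 0.293 with an estimated correlation, with Cdk1 (-0.49 ± 0.11). The costimulatory gene Cd86 (0.97 ± 0.11) rose, while the MHC class II list did not pass (camera adjusted p = 0.0802).

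The lysosomal membrane proteins passed in the upward direction (4 of 32 rose and 0 fell, 8 and 2 adjusted over the list alone, camera adjusted p = 0.00181 but adjusted p = 0.293 with an estimated correlation). So did the autophagy machinery (4 of 34 rose and 0 fell, 4 and 0 adjusted over the list alone, camera adjusted p = 0.00515 but adjusted p = 0.156 with an estimated correlation) and Rag GTPase and folliculin signalling (2 of 15 rose and 0 fell, 4 and 1 adjusted over the list alone, camera adjusted p = 0.0372 but adjusted p = 0.238 with an estimated correlation). Rragd (0.71 ± 0.09), Optn (0.45 ± 0.10) and Slc36a1 (0.37 ± 0.09) rose. The hydrolases went both ways (3 of 49 rose and 3 fell, 5 and 4 adjusted over the list alone, camera adjusted p = 0.447), with Ctsh (0.52 ± 0.09) higher and Psap (-0.46 ± 0.09) lower. V-ATPase subunits (0 of 18 rose and 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.502) and textbook MiT/TFE targets (3 of 23 rose and 2 fell, 7 and 2 adjusted over the list alone, camera adjusted p = 0.178) did not pass. Among genes of disease-associated microglia and lipid-associated macrophages, 3 of 21 rose and 5 fell (5 and 7 adjusted over the list alone), camera adjusted p = 0.0189 but adjusted p = 0.405 with an estimated correlation, with Gpnmb (-0.81 ± 0.09), Spp1 (-0.55 ± 0.07) and Lpl (-0.51 ± 0.10) lower and Apoe (0.55 ± 0.10) higher. Nuclear oxidative phosphorylation passed downward as a list (camera adjusted p = 2.8e-05 but adjusted p = 0.405 with an estimated correlation). Of its 56 genes 50 had a fold change below 0 and 17 an unadjusted p under 0.05, and edgeR, DESeq2 and limma-trend each called 0, as did edgeR adjusted over the list alone. Lipid uptake and droplets had a median of 0.11, a mean of -0.07 and a downward test that did not pass (camera adjusted p = 0.447). LXR targets had a mean of -0.01 and an upward test that did not pass (camera adjusted p = 0.501).

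In all, 13 of 27 lists passed (10 up and 3 down), 2 of them, alternative activation and complement, also with an estimated correlation. Without 1 library the count of genes was 308 (WT Rosa26 replicate 1), 262 (WT Rosa26 replicate 2), 266 (WT TKO replicate 2) or 268 (WT TKO replicate 4), against 515, and at most 750. It was 808 by DESeq2, 216 without the batch block and 1171 with a genotype-by-batch block, chosen after seeing the data.

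The fourth comparison asked what the loss of progranulin changed in edited macrophages (GrnKO against WT, TKO, n = 4 per group). Fewer genes passed than in Rosa26 cells: 390 rose and 377 fell, 767 in all, and 55 rose and 42 fell more than 2-fold. Cd28 rose from 9.94 ± 0.455 to 25.0 ± 4.95 CPM (SD), against 11.4 ± 3.38 and 91.0 ± 5.15 CPM in Rosa26 cells. Arg1 fell from 13.2 ± 2.83 to 5.34 ± 0.676 CPM and Cx3cr1 from 51.6 ± 17.7 to 18.2 ± 5.82 CPM. Lists of V-ATPase and lipid genes were higher in GrnKO cells, and those of ribosomal protein and complement genes were lower. With an estimated correlation these calls were lost, for V-ATPase subunits (adjusted p = 0.142), lipid uptake and droplets (adjusted p = 0.135), cholesterol synthesis (adjusted p = 0.227), ribosomal proteins (adjusted p = 0.148) and complement (adjusted p = 0.148).

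Large rises were found in Pakap, whose counts could be divided between its 2 identifiers (2.07 ± 0.13 and 2.03 ± 0.16), and in Igf2bp3 (1.54 ± 0.21), Fbln5 (1.39 ± 0.19), Cd28 (1.31 ± 0.14) and Itgb3 (1.31 ± 0.15), with an adjusted p of 2.7e-04 or less. The largest falls after Grn included Saa3 (-1.54 ± 0.27), Kazald1 (-1.54 ± 0.18), Cx3cr1 (-1.46 ± 0.32), F13a1 (-1.42 ± 0.19) and Arg1 (-1.30 ± 0.13), with an adjusted p of 0.0312 or less. The neighbours of Grn, chosen here after their values were seen, were Fam171a2 with 1.97 ± 0.24 (adjusted p = 7.7e-05) and Slc25a39 with 0.39 ± 0.07 (adjusted p = 0.00475).

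Of the V-ATPase subunits, 7 of 18 rose and 0 fell (12 and 0 adjusted over the list alone), camera adjusted p = 4.1e-07 but adjusted p = 0.142 with an estimated correlation, with Atp6v0a1 (0.42 ± 0.08) and Atp6v0d1 (0.34 ± 0.07). Of the lysosomal hydrolases, 8 of 49 rose and 3 fell (8 and 4 adjusted over the list alone), camera adjusted p = 0.0424 but adjusted p = 0.403 with an estimated correlation, with Scpep1 (0.57 ± 0.10) and Gla (0.40 ± 0.07) higher and Ctsc (-0.77 ± 0.14) lower. Of the lysosomal membrane proteins, 0 of 32 rose and 1 fell (1 and 1 adjusted over the list alone), camera adjusted p = 0.0213 but adjusted p = 0.338 with an estimated correlation, with a median of 0.10 and a mean of 0.10. The called gene was the metal transporter Slc11a1 (-0.52 ± 0.08). Among the textbook MiT/TFE targets, 5 of 23 rose and 0 fell (6 and 0 adjusted over the list alone), camera adjusted p = 3.0e-04 but adjusted p = 0.135 with an estimated correlation, and Gpnmb had 0.50 ± 0.09, adjusted p = 0.00331. Of the genes of lipid uptake and droplets, 5 of 15 rose and 0 fell (7 and 0 adjusted over the list alone), camera adjusted p = 1.2e-04 but adjusted p = 0.135 with an estimated correlation, with Fabp4 (0.96 ± 0.14) and Fabp5 (0.87 ± 0.16). Of those of cholesterol synthesis, 2 of 23 rose and 0 fell (2 and 0 adjusted over the list alone), camera adjusted p = 0.00528 but adjusted p = 0.227 with an estimated correlation, with Insig1 (0.46 ± 0.08). Of the cytosolic ribosomal proteins, 0 of 67 rose and 17 fell (0 and 49 adjusted over the list alone), camera adjusted p = 3.0e-20 but adjusted p = 0.148 with an estimated correlation, with Rps27 (-0.40 ± 0.07). Of the complement genes, 0 of 10 rose and 3 fell (1 and 5 adjusted over the list alone), camera adjusted p = 0.00528 but adjusted p = 0.148 with an estimated correlation, with C1qa at 953 ± 56.7 CPM in WT and 758 ± 28.8 in GrnKO.

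Of the macrophage identity genes, 1 of 17 rose and 4 fell (1 and 6 adjusted over the list alone), camera adjusted p = 0.0158 but adjusted p = 0.148 with an estimated correlation, with Itgam (-0.64 ± 0.12) and Lyz2 (-0.39 ± 0.07). Among inflammatory genes, 3 of 21 rose and 4 fell (4 and 7 adjusted over the list alone), camera adjusted p = 0.0454 but adjusted p = 0.234 with an estimated correlation, with Ptgs2 (-0.89 ± 0.15) lower and Ccl3 (0.98 ± 0.14) and Ccl4 (0.90 ± 0.09) higher. In MHC class II presentation, 1 of 9 rose and 0 fell (3 and 1 adjusted over the list alone), camera adjusted p = 0.0424 but adjusted p = 0.344 with an estimated correlation, with Cd80 (0.81 ± 0.17) the called gene. Among osteoclast genes, 2 of 10 rose and 0 fell (2 and 0 adjusted over the list alone), camera adjusted p = 0.0376 but adjusted p = 0.236 with an estimated correlation, with a median of -0.02, a mean of 0.28 and an upward test. Alternative activation did not pass (camera adjusted p = 0.0717), with a median of 0.03, a mean of -0.22 and a downward test. The remaining lists past the test upward were Rag GTPase and folliculin signalling (1 of 15 rose and 0 fell, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0158 but adjusted p = 0.148 with an estimated correlation) and disease-associated microglia genes (4 of 21 rose and 1 fell, 4 and 3 adjusted over the list alone, camera adjusted p = 0.0450 but adjusted p = 0.403 with an estimated correlation). So were interferon-stimulated genes (2 of 35 rose and 0 fell, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0426 but adjusted p = 0.527 with an estimated correlation) and cell cycle (2 of 35 rose and 0 fell, 2 and 0 adjusted over the list alone, camera adjusted p = 0.00641 but adjusted p = 0.438 with an estimated correlation). Immediate early genes passed downward (0 of 19 rose and 3 fell, 1 and 8 adjusted over the list alone, camera adjusted p = 0.0107 but adjusted p = 0.227 with an estimated correlation). With the 10 libraries of little Y-linked signal, chosen after seeing the data, the osteoclast and microglia means turned below 0. There only batch 1 holds both genotypes.

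In all, 17 of 27 lists passed (12 up and 5 down), and none passed with an estimated correlation by camera, where 7 lists had an unadjusted p under 0.05. By fry, 13 lists passed. Without 1 library the count of genes was 278 (WT TKO replicate 2), 309 (WT TKO replicate 3), 474 (WT TKO replicate 4), 314 (GrnKO TKO replicate 2) or 386 (GrnKO TKO replicate 4), against 767, and 9 lists passed without GrnKO TKO replicate 2. By DESeq2 1208 genes passed, without the batch block 345, and with only the 8 samples compared 488. The groups differed in Xist and Y-linked transcripts, which the 10 libraries of little Y-linked signal cannot test.

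The interaction of genotype and editing asked which genes responded to the edit differently in GrnKO and WT cells (n = 4 in each of 4 groups). A value below 0 means a more negative change with the edit in GrnKO than in WT. Dio2 stood at 1.40 ± 0.370 and 0.479 ± 0.178 CPM (SD) in WT Rosa26 and TKO, and at 65.6 ± 7.39 and 2.32 ± 0.756 CPM in the GrnKO pair. Pamr1 stood at 83.2 ± 41.1 and 87.2 ± 19.3 CPM in WT and at 12.0 ± 3.43 and 77.6 ± 17.6 CPM in GrnKO. The responses of lysosomal, V-ATPase and cholesterol genes were lower in GrnKO, and those of complement and ribosomal protein genes were higher. An estimated correlation ended the call for lysosomal hydrolases (adjusted p = 0.0855), the V-ATPase (adjusted p = 0.0969), complement (adjusted p = 0.0709) and ribosomal proteins (adjusted p = 0.314). The test called 2067 genes, 893 above 0 and 1174 below 0. Among those past 2-fold, 362 lay above 0 and 95 below 0. With limma-trend on the authors' CPM 627 lay above 0 and 2027 below 0 (23.6% above 0 against 43.2%).

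The interaction was lowest for Dio2 (-3.28 ± 0.36), Mgll (-2.89 ± 0.49), Adamts1 (-2.49 ± 0.29) and Cdkn1c (-2.22 ± 0.34) and among the highest for Pamr1 (2.57 ± 0.25) and Oprl1 (2.32 ± 0.41). In the lysosomal and autophagy lists it was below 0 for Naglu (-0.85 ± 0.12), Galns (-0.83 ± 0.16), Slc29a3 (-0.84 ± 0.11), Slc36a1 (-0.96 ± 0.13), Gabarapl1 (-1.03 ± 0.11) and Rragd (-0.68 ± 0.12). In the lipid lists it was below 0 for Hmgcs1 (-0.79 ± 0.13), Hilpda (-0.96 ± 0.13) and Fabp4 (-1.37 ± 0.19). It was above 0 for Ifi27l2a (1.40 ± 0.11), Folr2 (1.20 ± 0.09), Arg1 (1.13 ± 0.19), C1qa (0.61 ± 0.10) and Nr4a1 (1.00 ± 0.12) and below 0 for Hk2 (-0.90 ± 0.13) and Ier3 (-0.96 ± 0.14). All of these had an adjusted p of 0.00265 or less.

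Below 0 were the lysosomal membrane proteins (17 of 32 called below 0, 20 adjusted over the list alone, camera adjusted p = 1.0e-09). The lysosomal hydrolases were too (14 of 49 called below 0 and 0 above, 21 and 1 adjusted over the list alone, camera adjusted p = 1.1e-06 but adjusted p = 0.0855 with an estimated correlation), as were the V-ATPase subunits (8 of 18 called below 0, 10 adjusted over the list alone, camera adjusted p = 1.2e-05 but adjusted p = 0.0969 with an estimated correlation). So were the textbook MiT/TFE targets (9 of 23 called below 0, 13 adjusted over the list alone, camera adjusted p = 1.1e-06), cholesterol synthesis (12 of 23 called below 0, 17 adjusted over the list alone, camera adjusted p = 5.8e-10) and autophagy machinery (7 of 34 called below 0, 10 adjusted over the list alone, camera adjusted p = 0.00145 but adjusted p = 0.0709 with an estimated correlation). Rag GTPase and folliculin signalling was below 0 (3 of 15 called below 0 and 0 above, 8 and 1 adjusted over the list alone, camera adjusted p = 0.00885 but adjusted p = 0.0855 with an estimated correlation). LXR targets (1 of 11 called below 0, 2 adjusted over the list alone, camera adjusted p = 0.0125 but adjusted p = 0.314 with an estimated correlation) and lipid uptake and droplets (5 of 15 called below 0 and 3 above, 6 and 3 adjusted over the list alone, camera adjusted p = 0.0472 but adjusted p = 0.314 with an estimated correlation) were below 0 as well. The membrane proteins, MiT/TFE targets and cholesterol synthesis also passed with an estimated correlation. Above 0 were cytosolic ribosomal proteins (21 of 67 called above 0, 27 adjusted over the list alone, camera adjusted p = 2.8e-09 but adjusted p = 0.314 with an estimated correlation), complement (4 of 10 called above 0, 5 adjusted over the list alone, camera adjusted p = 0.00121 but adjusted p = 0.0709 with an estimated correlation) and alternative activation (3 of 9 called above 0, 3 adjusted over the list alone, camera adjusted p = 0.00298 but adjusted p = 0.0664 with an estimated correlation). Without 1 library the count of genes was 1233 (GrnKO Rosa26 replicate 1), 1294 (GrnKO Rosa26 replicate 2), 3608 (WT Rosa26 replicate 3), 1206 (WT TKO replicate 4) or 1252 (GrnKO TKO replicate 4), against 2067. It was 910 without the batch block and 3607 with the block for each genotype and batch.

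Markers of other cell types were few: 6 lists had under 5 tested genes and so no list test. The stromal gene Col1a2 had -1.36 ± 0.31, adjusted p = 0.00167 for the loss of Grn and 1.16 ± 0.30, adjusted p = 0.00661 for the edit in GrnKO. The lymphocyte genes Cd4 and Il7r rose with the loss of Grn (2.08 ± 0.20 and 0.87 ± 0.09) and fell with the edit in GrnKO (-1.63 ± 0.18 and -0.45 ± 0.09). The megakaryocyte gene Pf4, also expressed in macrophages, rose with the edit in WT (0.92 ± 0.09, adjusted p = 5.4e-06) and in GrnKO (1.31 ± 0.09, adjusted p = 4.7e-09) and fell with the loss of Grn (-0.91 ± 0.09 in Rosa26 and -0.52 ± 0.09 in TKO cells). The dendritic cell gene Batf3 rose with the loss of Grn in Rosa26 cells, as did the mast cell gene Kit (0.85 ± 0.29 and 1.19 ± 0.46). For the edit in GrnKO Batf3 had -1.26 ± 0.28, adjusted p = 0.00236, the mast cell and basophil gene Gata2 1.1 ± 0.40, adjusted p = 0.0441, and the neutrophil gene S100a8 -0.28 ± 0.14, adjusted p = 0.129.

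Across genes, the edit in GrnKO cells ran opposite to the loss of Grn. Of the genes that rose with the loss of Grn in Rosa26 cells, 2174 fell with the edit in GrnKO, where 632 would overlap in independent lists. Of those that fell, 1687 rose (489 in independent lists). The same direction was called in 15 genes that rose (524 in independent lists) and 7 that fell (589). Dio2, Mgll and Fabp4 rose with the loss of Grn in Rosa26 cells and fell with the edit in GrnKO. Arg1 and Cx3cr1 did the reverse. Pearson's r across the 15385 genes, which are not independent replicates, was -0.816 and Spearman's rho -0.793. Both contrasts use the GrnKO Rosa26 libraries, and simulated unchanged groups gave r = -0.448. The covariance was -0.305 against a simulated -0.0232, a difference of -0.282. With these libraries split between the contrasts, r was -0.706 and -0.676 and the covariance -0.332 and -0.227.

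**Figure D5:**
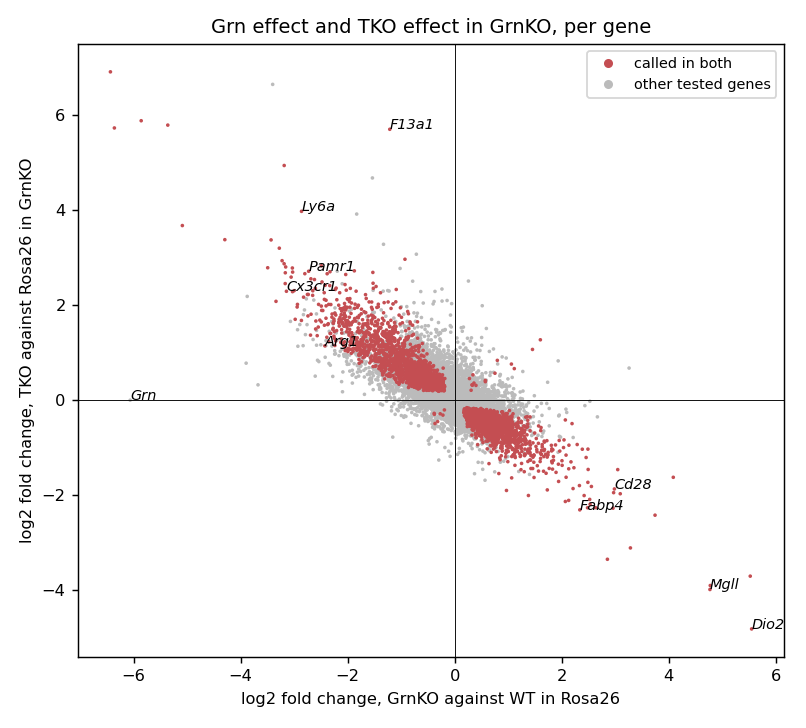
Log2 fold change per gene for the loss of Grn in Rosa26 cells (x axis) against the triple edit in GrnKO cells (y axis), for all genes tested, with genes called in both in red; both axes use the GrnKO Rosa26 libraries. Genes such as Dio2, Mgll and Fabp4 lie to the lower right, and Cx3cr1 and Ly6a to the upper left.

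The effect of Grn loss was smaller in edited cells. Of 6858 genes called in Rosa26 cells, 6704 (97.8%) had a smaller fold change in the same direction or an opposite one in TKO cells, and the median TKO fold change was 26.7% of that in Rosa26 on the log2 scale. Genes chosen for a call in Rosa26 cells are partly chosen for a high value there. Of 767 genes called in TKO cells, 528 (68.8%) were larger in Rosa26 cells, with a median TKO effect of 68.3% of that in Rosa26. The interaction called 1998 of the 6858 genes, all smaller or opposite in TKO, but the shared Rosa26 libraries favour that direction. Among rises, 341 genes were called in both edits (89.9 in independent lists) and among falls 303 (81.1), with 8 called in opposite directions. Across genes r was 0.494 and rho 0.487. The covariance was 0.110 against a simulated -0.000485, a difference of 0.111. The simulation and the independent lists leave out that Rosa26 and TKO libraries of 1 genotype and batch deviated together (mean correlations of 0.275 in WT and 0.276 in GrnKO), which adds a positive covariance to these contrasts with no effect of Grn.

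Some genes responded to the edit in both genotypes. Of 306 genes called in both, 265 moved in 1 direction (182 rose, among them F13a1, Ccl8, Ly6a, Cp and Lifr, and 83 fell, among them Gpnmb, Fabp4 and Cdkn1c) and 41 in opposite directions. Independent lists would share 49.6 rises and 31.9 falls. The interaction called 178 of the 515 genes called in WT and 1804 of the 5011 called in GrnKO. Slc36a1 and Rragd rose with the edit in WT, and in GrnKO Slc36a1 fell (-0.59 ± 0.09). Nr4a1, an immediate early gene, fell in WT (-0.41 ± 0.08) and rose in GrnKO (0.59 ± 0.08). Across all genes r was 0.198 and rho 0.116. The covariance was 0.0370 against a simulated -0.000140, a difference of 0.0372. With the 10 libraries of little Y-linked signal, chosen after seeing the data, r was -0.0480. Without WT Rosa26 replicate 3 it was 0.00296 and without WT TKO replicate 2 0.0702.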

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

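Of the tests in this part, those at equal depth, without a batch, with a block for each genotype and batch, of less editing in WT, of the state of the GrnKO Rosa26 wells and all of Xist and Y-linked transcripts were chosen only after the result was seen.

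The edit called 5011 genes in GrnKO and 515 in WT, 6225 and 1171 with a block for each genotype and batch, and 5095 and 808 by DESeq2 (by edgeR 308, 262, 266, 268 and 750 in WT without WT Rosa26 replicate 1, WT Rosa26 replicate 2, WT TKO replicate 2, WT TKO replicate 4 and WT Rosa26 replicate 3). The ratio was 7.89 at equal depth, 15.6 with batch 1, which holds the shallow WT Rosa26 replicate 1, left out of every group (3292 against 211), and 8.11 to 30.5 without each other batch, which argues against depth and that library as the whole cause. Less editing in WT cannot be told apart from a genotype effect, because mRNA levels do not measure editing and the interaction was 0.39 ± 0.24 for Tfe3 and 0.49 ± 0.13 for Mitf, where a value above 0 is a more negative change in WT. A biological hypothesis that stays open is that MiT/TFE factors may be more active without progranulin, so that their loss could change more genes. Sequencing the edited alleles and imaging TFEB and TFE3 in the nucleus would test both.

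The edit in GrnKO ran against the effect of Grn loss (r = -0.816 across genes). With the shared GrnKO Rosa26 libraries split, the smaller covariance was -0.227 against -0.305 unsplit, and at equal depth r was -0.818, which argues against shared libraries and depth as the whole cause. A state of the GrnKO Rosa26 wells alone cannot be told apart from an effect of genotype. The Grn effects in Rosa26 and TKO cells, which share no library, correlated at 0.494, but Rosa26 and TKO libraries deviate together by batch. Of 100 groupings, the real one included, 17 gave a value as large in size, 6 of them positive. The largest other in size was -0.786, and the largest other positive value was 0.655. A hypothesis that stays open is that genes raised without progranulin may depend on MiT/TFE factors. Cells from a separate thaw, with progranulin added back, would test it.

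Xist and Y-linked transcripts did not follow the male label in 10 libraries, and the WT libraries of batch 2 held both. Loss of the Y chromosome in culture is argued against by the lowest Xist level of the 10 libraries, 169 CPM, and exchange of indices between libraries by a Ddx3y level in the lowest library of 0.174% of that in the lower WT batch 2 library. Rosa26 and TKO libraries of 1 genotype and batch deviated together on autosomal genes (mean correlation 0.242, highest other pairing 0.211, exact permutation p = 0.00174), consistent with cells of 1 source for both. Source animals of either sex, pooled in WT batch 2, may explain the pattern, and mislabelled stocks stay open as well. Genotyping the frozen stocks for Y-linked sequence would tell these apart.

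In 7 of 96 groups of 4 libraries, 1 library lay far from the other 3, and chance gives about 1 in 20. These were the share of mitochondrially encoded counts in WT Rosa26 replicate 3 (1.31% against 1.54 to 1.56% in the group), Cd28 in GrnKO TKO replicate 1 (17.7 CPM against 26.7 to 28.4 CPM in the group), Fam171a2 in GrnKO Rosa26 replicate 4 (7.37 CPM against 5.24 to 5.48 CPM in the group) and Fam171a2 in GrnKO TKO replicate 1 (3.37 CPM against 4.84 to 4.95 CPM in the group). Further cases were C1qa in GrnKO Rosa26 replicate 2 (395 CPM against 311 to 325 CPM in the group), F13a1 in GrnKO TKO replicate 3 (12.6 CPM against 21.6 to 22.6 CPM in the group) and Grn in WT TKO replicate 1 (2522 CPM against 3125 to 3224 CPM in the group).

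Of 38 genes named for the same contrast in both genotypes or both edits, 23 responded differently by the interaction test of edgeR. The interaction (log2) was above 0 for Arg1 (1.13), C1qa (0.61), Cp (0.88), Cx3cr1 (1.69), Ifi27l2a (1.40), Itgam (0.82), Lifr (0.87), Ly6a (1.93), Mitf (0.49), Nr4a1 (1.00), Pf4 (0.38) and Rps27 (0.46). It was below 0 for Atp6v0d1 (-0.39), Cd28 (-1.67), Cdkn1c (-2.22), Fabp4 (-1.37), Fabp5 (-0.74), Gla (-0.48), Gstm1 (-0.50), Insig1 (-0.62), Itgb3 (-0.70), Slc36a1 (-0.96) and Slc40a1 (-0.95). By camera the response of 12 lists differed between the genotypes, of which 3 also passed with an estimated correlation, and 25 of 100 splits of the samples, the real one included, gave as many lists. The median interaction was below 0 for lysosomal hydrolases (-0.25), lysosomal membrane proteins (-0.40), V-ATPase subunits (-0.31), Rag GTPase and folliculin signalling (-0.31), autophagy machinery (-0.20), textbook MiT/TFE targets (-0.37), LXR targets (-0.33), cholesterol synthesis (-0.50) and lipid uptake and droplets (-0.10). It was above 0 for alternative activation (0.14), complement (0.39) and cytosolic ribosomal proteins (0.24).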

How the results depend on the processing

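Counts refined from both tables, equal depth, the 10 libraries with little Y-linked signal, no robust option and the block for genotype and batch were chosen after seeing the data.

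With DESeq2 the edit in WT called 808 genes against 515, and the loss of Grn in TKO cells 1208 against 767. With only the 8 samples compared the latter was 488, and the loss of Grn in Rosa26 cells called 5425 (main 6858). In that setting the edit called 680 genes in WT and 7152 in GrnKO (main 5011). Without the batch block counts were 216 for the edit in WT, 345 for the loss of Grn in TKO cells and 910 for the interaction (main 2067). There 99 calls of named genes and 6 of lists were also lost. With a block for each genotype and batch counts were 1171 for the edit in WT and 3607 for the interaction. Libraries that deviate together would shift the 8-sample and genotype-by-batch counts so. The cause was not tested.

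Leaving out each library gave 262 to 750 genes for the edit in WT, 278 to 839 for the loss of Grn in TKO cells and 1206 to 3608 for the interaction. The libraries that moved these counts by more than 1.5 times were, for the edit in WT, WT Rosa26 replicates 1 (308) and 2 (262) and WT TKO replicates 2 (266) and 4 (268). For Grn loss in TKO cells they were WT TKO replicates 2 (278), 3 (309) and 4 (474) and GrnKO TKO replicates 2 (314) and 4 (386). For the interaction they were GrnKO Rosa26 replicates 1 (1233) and 2 (1294), WT Rosa26 replicate 3 (3608), WT TKO replicate 4 (1206) and GrnKO TKO replicate 4 (1252). The edit in GrnKO (3520 to 5096) and the loss of Grn in Rosa26 cells (5784 to 7284) moved less.

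With an estimated correlation camera passed 2 of 13 lists for the edit in WT, 4 of 17 for it in GrnKO, 8 of 16 for the loss of Grn in Rosa26 cells, 0 of 17 for it in TKO cells (7 at an unadjusted p under 0.05, 13 by fry) and 3 of 12 for the interaction. By fry 7 lists passed for the edit in WT. Without 1 library 9 to 19 lists passed for the loss of Grn in TKO cells, the lowest without GrnKO TKO replicate 2.

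With the 10 libraries with little Y-linked signal, fewer samples were left, 112 genes were called for the loss of Grn in TKO cells, and r was -0.0480 for the edit in both genotypes (main 0.198) and -0.701 for the loss of Grn against the edit (main -0.816). The mean log2 fold change turned sign for lists of the loss of Grn in TKO cells: for genes of disease-associated microglia it was -0.0638 (main 0.0735, adjusted p = 0.872, over all alternatives 0.0134 to 0.872, main 0.0450). For genes of nuclear oxidative phosphorylation it was 0.117 (main -0.000556, adjusted p = 1.8e-04, over all alternatives 1.8e-04 to 0.999, main 0.997). For genes of osteoclasts it was -0.115 (main 0.279, adjusted p = 0.713, over all alternatives 0.00990 to 0.713, main 0.0376). For genes encoded in mitochondria it was -0.175 (main 0.00385, adjusted p = 4.3e-04, over all alternatives 4.3e-04 to 0.999, main 0.997). Leaving out single libraries gave an r of 0.00296 to 0.296 for the edit in both genotypes, and besides WT Rosa26 replicate 3 (the lowest), WT TKO replicate 2 moved it by more than 1.5 times (0.0702 without it).

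Of the named genes' calls, 34 of 79 for the edit in WT, 117 of 129 for it in GrnKO, 124 of 127 for the loss of Grn in Rosa26 cells, 38 of 79 for it in TKO cells and 60 of 97 for the interaction passed in all leave-outs and the settings chosen in advance, and no named gene changed sign with a call in any setting run. In simulation with the real library sizes, 20 of 100 genes changed 1.5-fold were recovered for the interaction and 55 for the edit in WT, with depth not varied. With all libraries thinned to the depth of the shallowest, 457, 3606, 5530, 625 and 1641 genes were called for the comparisons in the order above, with fewer genes tested.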

Other observations

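All tests in this part were planned, apart from the values of Y-linked genes, which were chosen after they were seen. In antigen presentation, the loss of Grn in Rosa26 cells came with higher H2-DMb1 (0.98 ± 0.11), a chaperone of peptide loading on MHC class II, and Cd80 (1.14 ± 0.17), a costimulatory ligand, while the list did not pass (2 of 9 rose and 0 fell, 2 and 0 adjusted over the list alone, camera adjusted p = 0.107, median 0.71). The edit in GrnKO lowered H2-DMb1 (-0.89 ± 0.11) and raised Cd86 (0.89 ± 0.10). Among genes of antioxidant and iron handling, the glutathione transferase Gstm1 rose with the loss of Grn (0.96 ± 0.10 in Rosa26 cells, 0.46 ± 0.10 in TKO cells) and fell with the edit (-0.63 ± 0.10 in WT, -1.13 ± 0.10 in GrnKO). The iron exporter Slc40a1 fell with the edit in GrnKO (-1.21 ± 0.10) and rose with the loss of Grn in TKO cells (0.78 ± 0.11). In the integrated stress response, Sesn2 (0.88 ± 0.12), Atf5 (0.74 ± 0.10) and Phgdh (0.96 ± 0.13) rose with the loss of Grn, where Phgdh starts serine synthesis, and the list did not pass (6 of 19 rose and 2 fell, 6 and 2 adjusted over the list alone, camera adjusted p = 0.176). Of the p53 targets, Cdkn1a (0.64 ± 0.10) rose and Gdf15 (-0.51 ± 0.11) fell with the edit in GrnKO, and the list did not pass (camera adjusted p = 0.128).

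Genes of large response outside the lists included the small adaptor gene Bex1 and the tetraspanin gene Tspan7, both on the X chromosome, which rose with the loss of Grn (5.52 ± 0.48 and 4.78 ± 0.35) and fell with the edit in GrnKO (-3.71 ± 0.36 and -3.91 ± 0.30). Tspan7 stood at 0.740 ± 0.399 CPM (SD, n = 4) in WT Rosa26 and 18.8 ± 0.633 in GrnKO Rosa26. Tmem176a and Tmem176b, which lie beside each other, rose with the edit in GrnKO (2.71 ± 0.31 and 2.42 ± 0.24). Among disease-associated microglia and lipid-associated macrophage genes, the loss of Grn in Rosa26 cells raised 8 of 21 and lowered 6, with Igf1 (-0.66 ± 0.07) and Tyrobp (-0.52 ± 0.07) lower and Fabp5 (1.60 ± 0.16) higher, and the list did not pass (camera adjusted p = 0.458). All the named changes in this and the paragraph before had an adjusted p under 0.05.

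The Y-linked genes other than Ddx3y followed it. They were Uty at 0.109 to 1.04 CPM in the 10 libraries, 7.44 to 8.88 in WT batch 2, 28.8 to 29.4 in WT batch 3 and 23.6 to 34.1 in GrnKO batch 4. Kdm5d lay at 0.385 to 0.821 CPM in the 10 libraries, 7.52 to 8.68 in WT batch 2, 17.1 to 17.7 in WT batch 3 and 18.5 to 25.2 in GrnKO batch 4. Eif2s3y lay at 0 to 0.499 CPM in the 10 libraries, 3.78 to 8.20 in WT batch 2, 30.1 to 45.9 in WT batch 3 and 20.9 to 29.6 in GrnKO batch 4.

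All 35 splits of the samples of each comparison were tested, and each count of splits includes the real one. Counted over splits that ignore the pairing by batch, the real one alone gave as many genes (1 of 35 in each). The highest other was 83 for the edit in WT (515 in the real split), 1839 for it in GrnKO (5011), 144 for the loss of Grn in Rosa26 cells (6858) and 11 for it in TKO cells (767). The split with 1839 genes exchanged GrnKO Rosa26 replicate 3 with GrnKO TKO replicate 2. Besides the real one, 7 splits part all 4 pairs of batch mates, too few for a share under 0.05, and the most genes in any of them was 144, for the loss of Grn in Rosa26 cells. For lists 3 of 35 splits gave as many for the edit in WT (highest other 16, against 13). For it in GrnKO 4 did (20, against 17), and for the loss of Grn in Rosa26 cells 3 (16, against 16). The other matching splits exchanged 1 library of each group and kept most of the real grouping, so chance is not decided. For the loss of Grn in TKO cells 1 of 35 splits gave as many lists, highest other 14, against 17. Among the splits that part all 4 pairs the most lists were 8, 16, 13 and 11.

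For the interaction, 3 of 100 splits drawn, with the edit redrawn within each genotype, gave at least 2067 genes. The 3 other splits that kept the GrnKO grouping and regrouped the WT libraries gave 2850, 2357 and 733 genes, and all others drawn gave 30 or fewer. These 3 set the GrnKO libraries, grouped as they were, against regrouped WT libraries. With the genotype redrawn within each edit, 2 of 100 gave as many genes, the highest other 4366, in a split that kept the Rosa26 grouping. These splits leave out that Rosa26 and TKO libraries of 1 genotype and batch deviated together. They set the count against no effect of the edit, or none of the genotype, not against an equal effect of the edit in both genotypes. Whether chance gives the interaction count is thus not decided. For its lists 25 of 100 gave as many, the highest other 21 against 12, but all kept 6 or more of 8 GrnKO labels. For these lists chance is not decided, and for the correlations it is not excluded. For the edit in both genotypes 32 of 100 splits gave an r as large in size (0.198, largest other in size -0.601). For the loss of Grn in both edits 17 of 100 did (0.494, largest other in size -0.786).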
